A study of Mus musculus with 3 samples.

How the data were processed

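The values analysed were UMI counts per gene and cell barcode, which the authors made with Cell Ranger 8.0.1, per the file headers, from Chromium GEM-X 3' v4 libraries and deposited as 1 sparse matrix per library with its gene identifiers, gene symbols and barcodes. The submitters' notes name the GRCm39 genome and FastQC 0.11.7. No barcode had fewer than 500 UMIs, so droplets without cells had been left out, and no correction for free RNA was recorded. The reference annotation at hand was for GRCm38, so no coordinates were used and genes were matched by identifier.

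Cells with at least 500 genes and at most 15% mitochondrial UMIs were kept. Doublets were called in each library by the share of simulated doublets (2 per cell) among 30 nearest neighbours, and the highest-scoring cells were removed at a rate of 0.4% per 1000 barcodes (5.81%, 7.07% and 7.59% of Cont, CIA and CIA+VFX). Counts were scaled to 10000 per cell and logged, 2000 variable genes were reduced to 40 principal components, and a graph of 20 neighbours was clustered by the Leiden method at resolution 1.5. No integration across libraries was applied. Clusters were named from markers of 23 cell types, and a cluster was left unnamed where no type reached the minimum score, where fewer than 3 markers were detected, where few UMIs met no own marker among the leading genes, or where the leading genes or scores pointed to another type or to 2 compartments. The thresholds of the naming score were set after the clusters had been seen. Markers, 32 gene lists, comparisons, filters and alternatives were fixed before the data were examined. The pairs of list and class that were described, their narrowing to 2 examples per list, and the grouping of clusters 9 and 16 were chosen later. The rule that this grouping decides nothing where those clusters gave most of the G2/M UMIs in both Cont and CIA was set after its value had been seen.

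UMIs were summed per library and class and given as CPM, counts scaled to a common total per class. A class was compared if every library had at least 50 of its cells, which held for 16 classes. The log2 ratio of CPM had an exact conditional binomial interval (95%) and no pseudocount. A pseudocount of 0.5 was used only in the correlations, covariances, Cont-side percents and distances that set venlafaxine against the model. Genes with at least 50 UMIs in the compared libraries counted as measured. A gene list was described by its median log2 ratio with an order-statistic interval and by its members at least 1.5-fold higher or lower. Its percentile among 10000 random lists matched on expression in 20 bins was also computed but is not given in the results. The median log2 ratio of all measured genes was computed per class. For some lists and classes where scaling by median-of-ratios moved list medians by over 0.1, it was given beside the list median or subtracted from it. Shares had exact (Clopper-Pearson) intervals. For shares of cycling cells each cell was thinned to 2000 UMIs, and cells with at least 2 UMIs of the G2/M phase list were counted.

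Named genes were taken by rule: in the 5 classes with the most cells in their smallest library, and in the fibroblast, dermal papilla, bulge and matrix classes, the 3 genes with the highest and the 3 with the lowest log2 ratio. They needed at least 100 UMIs and 50 CPM in the higher library and a CPM of at least 0.5 times that over all its kept cells. Mitochondrial, ribosomal, haemoglobin and unnamed genes were left out. Genes called furthest apart, above or below were ranked only within these limits. A ratio against 0 UMIs was bounded with 3 counts and given as "at least". To set venlafaxine against the model, CIA cells were split at random 20 times, with 20 simulated libraries without effect, and genes at least 2-fold apart in the model were counted on the Cont side or away from it.

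Alternatives were a stricter filter (1000 genes, 8% mitochondrial), no doublet removal, Leiden resolutions 0.8 and 2.5, classing of each cell by its own markers, TMM and median-of-ratios scaling, mean over cells, thinning, subtraction of 5% free RNA, minimum UMIs of 10 or 200, and shares within compartments (the endothelial and neural crest ones added after the shares were seen). The code ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, pandas 2.3.3 and matplotlib 3.10.9, and in R 4.3.3 with edgeR 4.0.16 for TMM factors, with random seed 1. Counts of matrix and hair shaft cells were simulated with counting error only and 1.5-fold differences. Of the intervals of changed genes, 80.7% excluded no difference for CIA against Cont and 71.4% for CIA+VFX against CIA.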

Results

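Dorsal skin of 9-week-old female C57BL/6 mice was measured by droplet single-cell RNA sequencing in 3 groups. These were vehicle-treated mice (Cont), mice of a chemotherapy-induced alopecia model (CIA), and mice of that model given venlafaxine (CIA+VFX). Each group had 1 library, made from skin pooled from an unstated number of mice after wax depilation, so n = 1 per group. The labels name neither the chemotherapy drug nor a dose or a day of sampling. The Cont library held 14529 barcodes and 143164803 UMIs (median 5950 UMIs and 2193 genes per barcode). The CIA library held 17675 barcodes and 130557879 UMIs (medians 4977 and 2028), and the CIA+VFX library 18987 barcodes and 155210692 UMIs (medians 4923 and 2047). The CIA library alone stood apart in mitochondrial UMIs, with medians of 2.32%, 1.42% and 2.40% per barcode in Cont, CIA and CIA+VFX and 1503, 503 and 1484 barcodes above the limit set for them. Over all barcodes Cont was the deepest, and the gap was wider within some classes: dermal papilla-like cells had median depths of 8160, 4631.5 and 4665 UMIs in Cont, CIA and CIA+VFX. In other classes CIA cells were deeper than Cont cells: medians were 19052 against 11253 UMIs in sebocyte-like, 16690 against 13277 in suprabasal keratinocyte-like and 10129 against 8510 in upper follicle keratinocyte-like cells.

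Of the 3 questions, the first was which cells and transcripts differed in the model (CIA against Cont). The second was which differed with venlafaxine in the model (CIA+VFX against CIA). The third was what remained different from vehicle-treated skin (CIA+VFX against Cont). After filters on genes and mitochondrial UMIs, 12638, 16573 and 16635 cells remained in Cont, CIA and CIA+VFX. Removal of 734, 1172 and 1263 cells called as doublets left 11904, 15401 and 15372. The kept cells formed 58 clusters, of which 47 could be called by cell type markers and were joined into 19 classes. The thresholds for naming were set after the clusters had been seen. The 11 unnamed clusters, referred to by number, held 20.4%, 18.8% and 23.7% of the kept cells of Cont, CIA and CIA+VFX. Markers, gene lists, comparisons and the rule for named genes were fixed before the data were examined, whereas the pairs of list and class described below were picked after their values were seen. With 1 library per group no test across replicates was possible, and no replicate check stands behind any difference. The intervals given, exact binomial ones for shares and levels and order-statistic ones for list medians, cover counting error or the spread over genes only. Some named genes were leading genes of clusters outside the class in which they are given, among them Prg4, Aldh3a1, Akr1c18 and Cldn10 in fibroblast-like, Tagln, Acta2 and Pinlyp in bulge-like, Serpinb2 and Tchh in matrix and hair shaft-like and Ccl5 in macrophage and monocyte-like cells, and for such genes, cells or RNA of other types are not excluded. With 1 library per group, a cluster mostly of 1 library may be that library rather than a cell type.

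In the model, cells of the growing hair follicle made up a smaller part of the skin suspension, and vascular and granulocytic cells a larger part. Inner root sheath-like cells, which form the sheath that moulds the hair shaft, were 6.93% of kept cells in Cont (6.48% to 7.40%) and 1.84% in CIA (1.63% to 2.06%), a ratio of 0.265 (0.231 to 0.304). Matrix and hair shaft-like cells were 2.23% in Cont (1.98% to 2.52%) and 1.05% in CIA (0.891% to 1.22%). Vascular endothelial-like cells were 1.54% in Cont (1.32% to 1.77%) and 6.05% in CIA (5.67% to 6.43%), 3.93-fold higher (3.35 to 4.63). Pericyte and smooth muscle-like cells, which surround small vessels, were 2.67-fold higher. Neutrophil-like cells were 24 of the kept cells in Cont and 184 in CIA (0.202% and 1.19%), and mast cell and basophil-like cells were 22 and 140 (0.185% and 0.909%). Melanocyte-like cells were 1.34% in Cont and 0.649% in CIA, a ratio of 0.486. Fibroblast-like cells were 10.3% and 14.0%, dermal papilla-like cells 4.58% and 5.25%, and sebocyte-like cells 1.13% and 1.55%. Bulge, outer root sheath and companion layer-like cells, here called bulge-like, were 9.59% and 7.63%. Macrophage and monocyte-like cells were 16.8% and 15.6%, and T, NK and innate lymphoid-like cells 14.8% and 10.9%.

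Shares are coupled, since they add up to the cells a digestion releases: the epithelial compartment, unnamed clusters included, was 36.9% of Cont and 27.4% of CIA cells, and the mesenchymal one 18.9% and 28.3%. Within the epithelial compartment the ratios of CIA to Cont were 0.357 for inner root sheath-like and 0.631 for matrix and hair shaft-like cells, so both stayed lower. Bulge-like cells turned from a lower to a slightly higher share there (1.07), and to 1.27 of all kept cells when each cell was classed by itself. Macrophage and monocyte-like cells turned to 1.07 within the immune compartment, and dermal papilla-like and fibroblast-like cells turned from higher to lower within the mesenchymal one (0.765 and 0.907). The vascular endothelial ratio was 1.42 within the endothelial compartment, a denominator added after the shares were seen. With cells classed one by one, the ratio was 0.752 for matrix and hair shaft-like, 3.30 for neutrophil-like and 2.41 for mast cell and basophil-like cells.

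**Figure D1:**
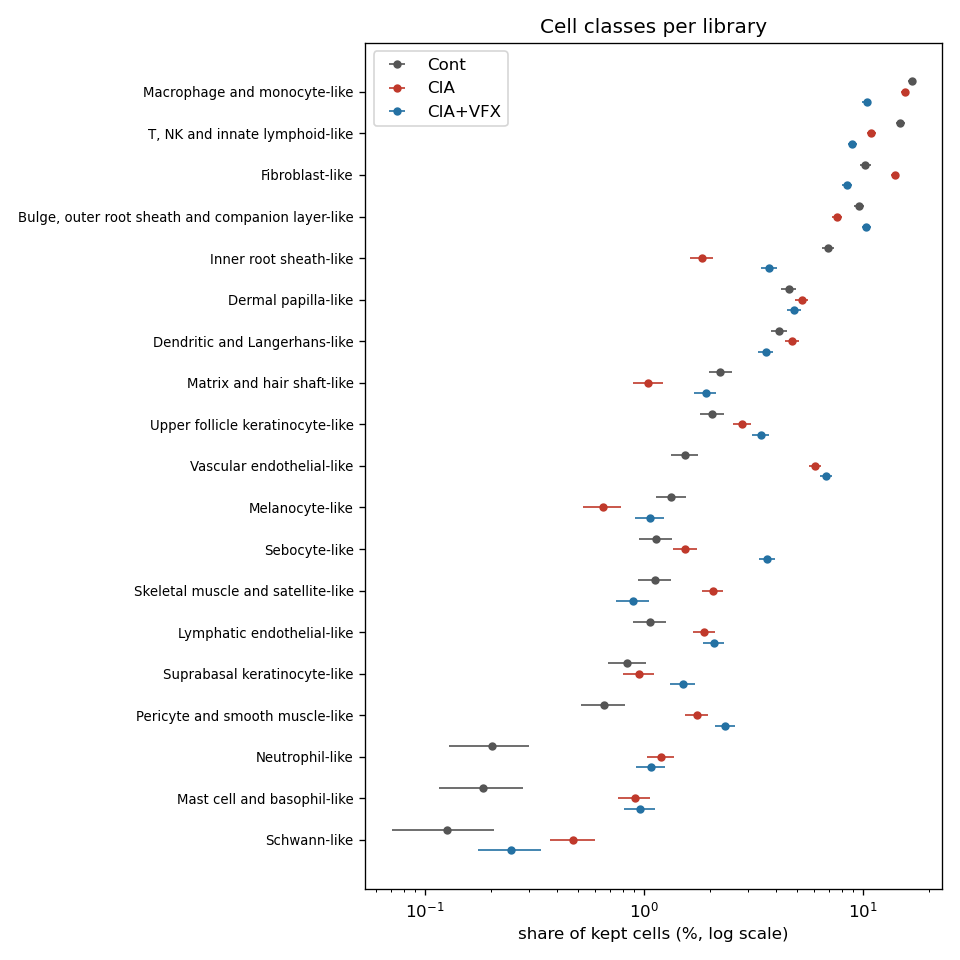
Share of kept cells (percent) in each named class in the Cont, CIA and CIA+VFX libraries, with exact 95% binomial intervals as bars. Inner root sheath-like cells were 6.93%, 1.84% and 3.73%, and vascular endothelial-like cells 1.54%, 6.05% and 6.79%, in Cont, CIA and CIA+VFX.

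Among keratinocytes, transcripts of injured epidermis were far higher in CIA than in Cont in the follicle opening and epidermis, whereas transcripts of dividing cells differed little over all keratinocytes and more within single classes. Over all keratinocytes, here every cell of the epithelial compartment, the 40 measured genes of the G2/M phase list, which act around mitosis, had a median log2 ratio of 0.29 (0.18 to 0.37). Of them 4 were at least 1.5-fold higher and 0 lower, with Hmmr at 37.7 against 22.0 CPM (1.71-fold) and Cenpf, a kinetochore protein, at 73.1 against 43.8 (1.67-fold). The S phase list, of DNA replication genes, had a median of 0.04 (-0.02 to 0.11), with Ung 1.87-fold and Gins2 1.65-fold higher. Ung turned to a log2 ratio of -0.04 after thinning of cells to a common depth. In upper follicle keratinocyte-like cells, 27 of 39 G2/M genes were at least 1.5-fold higher (median 0.85, 0.60 to 1.04), and in inner root sheath-like cells 9 of 39 (0.36, 0.25 to 0.50). The S phase medians were 0.46 and 0.25 in these classes. At a coarser clustering the G2/M and S phase medians of inner root sheath-like cells turned to -0.63 and -0.65.

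In bulge-like cells, the G2/M list had a median of 2.11 (1.70 to 2.32), with 35 of 37 genes at least 1.5-fold higher, Mki67 at a log2 ratio of 2.45 and an S phase median of 1.02. This class held 1142 Cont, 1175 CIA and 1592 CIA+VFX cells, and clusters 9 and 16, unnamed clusters with cell cycle genes among their leading genes, held another 703, 405 and 1089 (5.91%, 2.63% and 7.08% of kept cells). With these cells added to the class, a grouping chosen after their leading genes were seen, the G2/M median was 0.33 (0.23 to 0.45). Clusters 9 and 16 then gave 83.7% of the G2/M UMIs of Cont and 69.7% of those of CIA, and their nearest classes were matrix and hair shaft and basal keratinocyte rather than bulge. When each cell was classed by itself rather than by cluster, the G2/M and S phase medians of the bulge-like class turned to -0.10 and -0.04, and Mki67 to -0.35. Thinning to a common depth gave a G2/M median of 1.36. After thinning to 2000 UMIs per cell, 40.1% of Cont and 47.1% of CIA bulge-like cells had at least 2 UMIs of G2/M genes, leaving out 41 and 55 cells that were too shallow (89.2% and 86.4% unthinned); with cells classed one by one the ratio of these shares turned to 0.934. Over all keratinocytes the values were 55.0% and 54.0%, leaving out 453 and 635 cells (82.6% and 78.0% unthinned). In fibroblast-like cells, which divide less, the thinned shares were 7.55% and 8.92%.

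**Figure D2:**
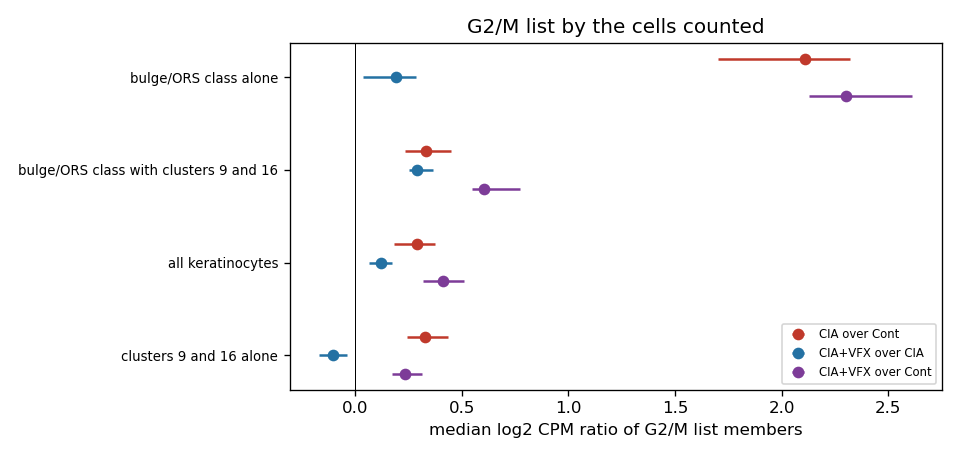
Median log2 ratio of the G2/M phase list by set of keratinocytes for the 3 comparisons of the Cont, CIA and CIA+VFX libraries, with order-statistic intervals over genes as bars. For CIA over Cont the median was 2.11 in the bulge-like class alone, 0.33 with clusters 9 and 16 added, and 0.29 over all keratinocytes.

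The wound and stress keratinocyte list was higher in CIA in suprabasal keratinocyte-like cells (median 3.42, 0.72 to 4.43, 17 of 23 genes higher and 3 lower) and in upper follicle keratinocyte-like cells (1.23, 0.46 to 2.45, 16 higher and 1 lower). In the latter, Stfa1 was at 108 against 2.44 CPM (44.4-fold) and Stfa3 at 465 against 20.2 (23.04-fold); both encode stefin A cysteine protease inhibitors. In suprabasal keratinocyte-like cells the cornified envelope and barrier list had a median of -0.26 (-0.67 to 0.10; 0.14 as a mean over cells), with 5 genes higher and 12 lower. Lor, the gene of loricrin, was at 2.01 against 117 CPM (57.9-fold lower), and Flg2, a filaggrin family gene, had 0 UMIs in CIA against 124 in Cont (at least 55.4-fold lower against a floor of 3 counts). The median gene of this class lay at -0.21, and relative to it the cornified envelope median was -0.05 and the wound median 3.62. Dissociation and immediate early genes were lower in the same cells (-0.64, -0.79 to -0.37). Inner root sheath keratins and trichohyalin (Tchh), of another cell type, summed to 95.9 CPM in this class in CIA against 621 in Cont.

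In the inner root sheath-like cells of CIA, 8 of 14 inner root sheath genes were at least 1.5-fold higher and 1 lower, with an interval that included 0 (median 0.75, -0.05 to 1.38), and with trichohyalin, Tchh, at 7856 against 2326 CPM (3.38-fold) and Krt27 at 2751 against 1037 (2.65-fold). Cluster 28, with Tchh and Krt27 among its leading genes, held 30.2% of this class in Cont and 47.3% in CIA. Hair shaft keratins and partners in matrix and hair shaft-like cells had a median of 0.10 (-0.15 to 0.56). Selenbp1 was 3.34-fold higher there, and the hair keratin Krt32 was 2.18-fold lower but had a log2 ratio of 0.29 after thinning. The genes of the same class furthest apart were Tchhl1 (6.51-fold higher), Ivl (4.07) and Tchh (2886 against 722 CPM, 3.995-fold higher), and Serpinb2 (2.62-fold lower), Eya1 (2.61) and Krtap15 (2.29). Ivl and Tchh turned to log2 ratios of -2.70 and -1.94 when cells were classed one by one. Inner root sheath keratins and Tchh summed to 3394 CPM in this class in CIA against 1349 in Cont. Tchh itself gave 2886 and 722 CPM of these sums, so they are not a measure apart from Tchh. Over all keratinocytes Shh, the hedgehog ligand of the growing bulb, had a log2 ratio of -0.94, with UMIs in 2.66% of Cont and 1.304% of CIA cells (median depths 10838 and 6220 UMIs), against 0.0502% and 0.0835% of macrophage and monocyte-like cells (6107 and 4909.5).

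In bulge-like cells the hair follicle stem cell list had a median of 0.12 (-0.12 to 0.44), and the median gene of the class lay at 0.19. Its members Krt15 (2.86-fold) and Gli1 (2.30-fold) were higher in CIA. Furthest apart in this class were the smooth muscle genes Tagln (307 against 21.1 CPM, 14.5-fold) and Acta2 (10.5-fold) and the homeobox gene Cux1 (8.77-fold), and, lower in CIA, Ivl (3.64-fold), the bicarbonate cotransporter Slc4a4 (3.45-fold) and Plagl1 (3.10-fold). With cells classed one by one, Cux1 and Plagl1 turned to -0.23 and 0.30. Targets of p53, the damage-induced transcription factor, had a median of 0.26 in bulge-like cells (0.05 to 0.91, 10 of 27 higher and 1 lower; 0.08 relative to the median gene). Medians of p53 targets were -0.02 in upper follicle keratinocyte-like, -0.01 in suprabasal keratinocyte-like, 0.02 in matrix and hair shaft-like, 0.06 in inner root sheath-like and 0.10 in dermal papilla-like cells. The p53-induced cell cycle inhibitor Cdkn1a had a log2 ratio of -0.34 in bulge-like cells.

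In the dermis of the model, fibroblast-like cells showed more p53 target transcripts. The p53 target list in fibroblast-like cells had a median of 0.40 (0.07 to 0.90, 13 of 31 higher and 1 lower), with Phlda3 at 53.3 against 14.8 CPM (3.60-fold), Eda2r at 28.3 against 8.44 (3.35-fold) and Cdkn1a at a log2 ratio of 0.43. The G2/M list had a median of 1.01 there (0.46 to 1.45, 14 of 22 higher and 1 lower; 0.24 without removal of doublets) and the S phase list 0.16. Mup20 (66.0 against 2.36 CPM, 28.0-fold), the acute-phase gene Saa3 (99.7 against 4.36, 22.9-fold) and lubricin, Prg4 (4.60-fold), were the genes furthest above Cont. Aldh3a1 (7.53-fold), Ndufa4l2 (84.4 against 423 CPM, 5.01-fold) and Cldn10 (4.76-fold) were furthest below. The collagen and matrix list had a median of -0.01 (-0.27 to 0.26), with tenascin C, Tnc, 4.56-fold and Timp1 2.98-fold higher. Wnt pathway genes had a median of -0.28 (-0.61 to 0.03, 1 of 27 higher and 8 lower), with the Wnt inhibitor Apcdd1 3.32-fold and Wnt5a 2.96-fold lower. The BMP and TGF-beta pathway (-0.10) and the FGF, IGF, PDGF and VEGF growth factors (-0.05) had medians near 0, with the BMP antagonist Grem1 at 32.6 against 142 CPM (4.37-fold lower), Inhba 2.25-fold higher, Igfbp5 2.98-fold lower and Igfbp4 2.43-fold higher. Cluster 12, of which Grem1 and Ndufa4l2 were leading genes, held 42.4% of fibroblast-like cells in Cont and 15.4% in CIA, where cluster 4 held the most (44.5%).

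Dermal papilla-like cells, the signalling centre of the follicle, had slightly more of their signature transcripts, with a median of 0.27 (0.10 to 0.50, 8 of 33 genes higher and 3 lower; 0.17 relative to the median gene of the class). The Wnt modulator Dkk2 (537 against 1438 CPM, 2.68-fold) and Bmp3 (2.43-fold) were lower. Furthest apart were Pde10a (5.59-fold), Luzp2 (3.93-fold) and the heat shock gene Hsph1 (3.41-fold) above Cont. Matrix Gla protein, Mgp (20.04 against 292 CPM, 14.6-fold), Col8a1 (11.2-fold) and pleiotrophin, Ptn (37.4 against 372 CPM, 9.96-fold), lay below. Mgp was also a leading gene of unnamed mesenchymal cluster 10 (1.58% of Cont and 4.18% of CIA cells) and Ptn of cluster 9 (3.26% and 1.55%), so cells or RNA from outside the class are not excluded. Dissociation and immediate early genes had a median of 0.07 in this class. Medians were -0.08 for the Wnt list, 0.12 for the BMP and TGF-beta list, 0.15 for growth factors, -0.01 for collagen and matrix, 0.05 for G2/M and -0.02 for S phase genes. Corin, a protease made by dermal papilla cells, had a log2 ratio of -0.03, with UMIs in 88.1% of Cont and 83.5% of CIA cells of the class (median depths 8160 and 4631.5 UMIs), against 3.59% and 2.13% of bulge-like cells (11211 and 7972).

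Macrophage and monocyte-like cells of the model contained more cells of cluster 1, led by Chil3 and the monocyte gene Ly6c2. Of the macrophage repair state list, Chil3 was higher and Retnla lower. Ly6c2 was at 617 against 32.2 CPM (19.1-fold, 17.4 to 21.1), Chil3 at 250.3 against 14.3 (17.4-fold) and haptoglobin, Hp, at 254 against 14.7 (17.3-fold), while Retnla was at 2007 against 16051 CPM (7.998-fold lower). Cluster 1 held 9.93% of the class in Cont and 57.9% in CIA, and cluster 13, with Retnla among its leading genes, 39.8% and 6.14%. Within cluster 3, which held 44.9% and 32.3%, Retnla was 4.42-fold lower. Slc39a12 (27.4-fold), Upb1 (13.2-fold) and Tenm4 (10.3-fold) were furthest below Cont. The list of inflammatory cytokines and chemokines was lower (median -0.38, -1.04 to -0.12, 2 of 36 genes higher and 16 lower; -0.54 relative to the median gene, which lay at 0.16), with Cxcl9 9.92-fold and Ccl22 5.07-fold lower. The macrophage repair state list, which holds both Chil3 and Retnla, had a median of 0.43 (-0.07 to 1.29, 9 of 22 higher and 1 lower). Interferon response genes, with a median of 0.39 (-0.27 to 0.71), went both ways (17 higher and 8 lower), and Ifit1 was 4.79-fold lower.

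In T, NK and innate lymphoid-like cells, Pde10a (4.19-fold), the cytokine gene Il17f (262 against 74.8 CPM, 3.50-fold) and Kcnma1 (3.24-fold) were above Cont. Granzyme A, Gzma (59.0 against 653 CPM, 11.1-fold), and the NK receptor genes Klra8 (10.6-fold) and Klra4 (9.67-fold) were below. Cluster 15, with Il17f among its leading genes, held 16.8% of the class in Cont and 27.2% in CIA, and cluster 45, with Gzma, Klra8 and Klra4 among its own, 11.4% and 3.03%. Cluster 50, with Kcnma1 among its leading genes, held 1.47% and 4.93%, and cluster 18 the most in Cont (23.03%). In vascular endothelial-like cells, angiogenesis and endothelial activation genes had a median of 0.01 (-0.20 to 0.20, 3 of 24 higher and 1 lower). Apln, an endothelial peptide of growing vessels, was 7.20-fold higher (2.73 to 26.9) but had only 4 UMIs in Cont against 108 in CIA. The adhesion molecule Icam1 was 2.03-fold higher. The median gene of vascular endothelial-like cells lay at 0.15. Among 45 pairs of keratinocyte lists and classes set in advance, 14 had an interval above 0 and 3 below it, and among 16 pairs in fibroblast-like and dermal papilla-like cells 3 and 0. Counts were also simulated for fibroblast-like cells from a profile pooled over the libraries, with counting error only. The 2-fold differences put in for CIA against Cont were all recovered in the right direction, and 95.8% of intervals held the true ratio. With no variation between cells, mice or libraries in the draws, this checks the interval calculation alone.

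With venlafaxine in the model, follicle and sebaceous cells took a larger share of the suspension and fibroblast-like and immune cells a smaller share. Inner root sheath-like cells were 3.73% of CIA+VFX cells (3.44% to 4.05%) against 1.84% of CIA cells, 2.03-fold higher, and matrix and hair shaft-like cells 1.91% (1.70% to 2.14%) against 1.05%, 1.83-fold higher. Sebocyte-like cells, which make the lipid of sebum, were 3.64% (3.35% to 3.95%) against 1.55%, 2.36-fold higher, and melanocyte-like cells 1.07% against 0.649%. Fibroblast-like cells were 8.45% against 14.0% (a ratio of 0.606), macrophage and monocyte-like cells 10.4% against 15.6% (0.668), and T, NK and innate lymphoid-like cells 8.95% against 10.9% (0.818). Vascular endothelial-like cells (6.79% against 6.05%), neutrophil-like cells (1.07% against 1.19%) and mast cell and basophil-like cells (0.956% against 0.909%) had shares close to those of CIA. The epithelial compartment, unnamed clusters included, was 43.4% against 27.4%, and within it the ratios were 1.28 for inner root sheath-like, 1.16 for matrix and hair shaft-like and 1.49 for sebocyte-like cells. Bulge-like cells were 10.4% against 7.63% of all kept cells but had a ratio of 0.857 within the epithelial compartment, and T, NK and innate lymphoid-like cells one of 1.09 within the immune compartment.

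In matrix and hair shaft-like cells, genes of hair keratins and their partners went both ways between CIA+VFX and CIA: 11 of 24 were at least 1.5-fold higher and 5 lower, with a median of 0.31 (-0.18 to 1.71) that was -0.19 after thinning. The genes of this class furthest above CIA were Krtap15, which is outside that list, Krt33b and Krt81. They were at 341 against 24.6 CPM (13.9-fold), 146 against 12.7 (11.5-fold) and 107 against 12.7 (8.43-fold). With 56.3, 4.26 and 3.65 CPM in Cont, all of them were higher in CIA+VFX than in either other library. The inner root sheath genes Tchhl1 (3.26-fold) and Tchh (944 against 2886 CPM, 3.06-fold) and the envelope gene Ivl (6.13-fold) were lower in the same class, and all 3 turned to higher (2.14, 3.13 and 2.84) when cells were classed one by one. Inner root sheath keratins and Tchh summed to 1341 CPM in this class against 3394 in CIA, of which Tchh itself gave 944 and 2886. In inner root sheath-like cells, the inner root sheath list was lower than in CIA (median -0.56, -0.89 to -0.07, 0 of 14 higher and 7 lower), with Krt72 2.69-fold and Krt71 1.95-fold lower, and cluster 28 held 42.9% of the class against 47.3%. Shh over all keratinocytes had a log2 ratio of 1.22 and UMIs in 2.45% of CIA+VFX cells against 1.304%. Lef1, a Wnt effector of the hair shaft lineage, had a log2 ratio of 0.29 in matrix and hair shaft-like cells.

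The G2/M list over all keratinocytes had a median of 0.12 (0.07 to 0.17) and the S phase list 0.16 (0.13 to 0.20), with Bub1 1.46-fold, Ttk 1.32-fold, Hells 1.37-fold and Blm 1.32-fold higher. Thinned shares of all keratinocytes with at least 2 UMIs of G2/M genes were 58.2% against 54.0% (1106 and 635 cells too shallow; 80.1% and 78.0% unthinned). In bulge-like cells the G2/M and S phase medians were 0.19 and 0.12 (G2/M -0.24 at a coarser clustering). The clusters of this class differed in direction, with G2/M medians of -0.44 (-0.64 to -0.30) in cluster 2, 0.68 (0.48 to 1.21) in cluster 19 and -0.01 in cluster 22. In upper follicle keratinocyte-like cells the G2/M and S phase medians were -0.47 (-0.57 to -0.35) and -0.25; the G2/M value of the latter was 0.03 with cells classed one by one. In inner root sheath-like cells the G2/M and S phase medians were 0.04 and 0.02. The wound and stress list had medians of -0.24 in upper follicle keratinocyte-like cells (-0.63 to -0.12, 1 of 24 higher and 9 lower) and -0.52 in suprabasal keratinocyte-like cells (-1.29 to 0.25). In upper follicle keratinocyte-like cells Sprr2a3, a cornified envelope precursor, was 2.05-fold and lipocalin 2, Lcn2, 1.68-fold lower.

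In suprabasal keratinocyte-like cells, the cornified envelope list had a median of 0.06, with the epidermal keratin Krt77 3.87-fold and the lipoxygenase Aloxe3 1.91-fold higher. Inner root sheath keratins and Tchh summed to 658 CPM in this class in CIA+VFX against 95.9 in CIA. In bulge-like cells p53 targets had a median of -0.16 (-0.31 to -0.11, 1 of 31 higher and 5 lower) and the stem cell list -0.11 (-0.65 to 0.04), with Nfatc1 2.56-fold and Foxc1 2.25-fold lower. The class was also made up differently: cluster 22, with Krt15 among its leading genes, held 14.3% of it in CIA+VFX and 26.3% in CIA, and cluster 19 held 29.1% and 19.5%. Pinlyp (3.42-fold), the kinase gene Dclk1 (1.97-fold) and Kiz (1.95-fold) were furthest above CIA in bulge-like cells, and Sox5 (2.89-fold), Tagln (2.83-fold) and the water channel Aqp3 (2.67-fold) furthest below. Pinlyp turned to a log2 ratio of -2.31 and Sox5 to 0.21 with cells classed one by one. Medians of p53 targets were 0.05 in upper follicle keratinocyte-like, -0.05 in suprabasal keratinocyte-like, 0.03 in matrix and hair shaft-like and 0.01 in inner root sheath-like cells. Inner root sheath keratins and Tchh, of another cell type, summed to 114 CPM in fibroblast-like cells of CIA+VFX and 55.4 in those of CIA. Whether free RNA or misplaced cells gave them was not tested.

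In fibroblast-like cells of CIA+VFX, p53 target transcripts were lower than in CIA (median -0.25, -0.51 to -0.09, 1 of 31 higher and 7 lower; -0.35 relative to the median gene, which lay at 0.10). Among them the ion channel gene Ano3 was 1.85-fold lower and Perp 2.06-fold higher, and Cdkn1a had a log2 ratio of -0.72. Cluster 20, with Ano3 among its leading genes, held 12.6% of fibroblast-like cells in CIA+VFX and 20.5% in CIA. The G2/M list was higher (0.45, 0.28 to 0.72, 11 of 26 genes higher and 0 lower), as was S phase (0.21). Within the UMI and CPM limits for named genes, the BMP antagonist Grem1 (2.02-fold), Angptl1 (1.82-fold) and the endothelin receptor Ednrb (485 against 270.1 CPM, 1.79-fold) were furthest above CIA. Procr (2.61-fold), Akr1c18 (2.19-fold) and the interferon-induced gene Isg15 (2.13-fold) were furthest below within the same limits. Ednrb turned to a log2 ratio of -0.08 at a coarser clustering. Collagen and matrix genes had a median of 0.12 (0.05 to 0.21), or 0.02 relative to the median gene, with Col3a1 1.53-fold higher and Tnc 1.55-fold lower. Medians were 0.19 for Wnt genes (Wnt5a 1.51-fold higher, Sfrp2 1.42-fold lower), 0.07 for BMP and TGF-beta genes (Bmp8a 2.17-fold lower) and -0.10 for growth factors (Igfbp3 1.73-fold lower).

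In dermal papilla-like cells, the genes furthest above CIA in CIA+VFX encode a decoy receptor, a semaphorin and an ion cotransporter: Tnfrsf11b was at 96.9 against 28.4 CPM (3.41-fold), Sema5a at 145 against 48.3 (2.997-fold) and Slc12a1 at 57.8 against 19.6 (2.95-fold). The peptide transporter gene Slc15a2 (4.48-fold), the chemokine Ccl2 (74.3 against 285 CPM, 3.84-fold) and Gria4 (2.26-fold) were lower. The dermal papilla signature had a median of 0.11 (-0.09 to 0.27), with Bmp3 1.98-fold and Dkk2 1.70-fold higher, the reverse of the model, and Corin had a log2 ratio of 0.46. Of clusters 7 and 46, both with Corin among their leading genes, the former held 63.9% of the class in CIA+VFX and 69.1% in CIA, and the latter 21.7% and 8.29%. Wnt pathway genes had a median of 0.13 (0.07 to 0.28, 2 of 28 higher and 0 lower). Medians were -0.02 for p53 targets, -0.05 for BMP and TGF-beta, 0.02 for growth factors, -0.04 for collagen and matrix, -0.04 for G2/M and -0.10 for S phase genes.

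Macrophage and monocyte-like cells of CIA+VFX differed less from CIA than CIA did from Cont. Ccl5 (1.89-fold), Morrbid (1.81-fold), a long noncoding RNA of myeloid cell survival, and Ceacam1 (1.77-fold) were furthest above CIA. Within the UMI and CPM limits for named genes, the stress cytokine Gdf15 (164 against 499 CPM, 3.05-fold), Slfn4 (2.57-fold) and Gstp1 (1.90-fold) were furthest below. Medians were -0.01 for inflammatory cytokines and chemokines (Cxcl1 1.55-fold lower), -0.24 for the repair state list (-0.58 to 0.08; Gpnmb 2.31-fold and Cd209f 1.72-fold lower) and -0.14 for interferon response genes (-0.30 to 0.03; Ifi44 1.95-fold and Usp18 1.83-fold lower). Cluster 1 held 54.1% of the class in CIA+VFX and 57.9% in CIA. In T, NK and innate lymphoid-like cells, S1pr1, a receptor of lymphocyte egress (2.05-fold), Cntn1 (1.99-fold) and Tmem71 (1.92-fold) were higher, and Slc15a2 (5.55-fold), Il17f (49.9 against 262 CPM, 5.25-fold) and Sema6a (2.62-fold) lower. Cluster 15 held 19.8% of that class against 27.2%. Angiogenesis and endothelial activation genes in vascular endothelial-like cells had a median of -0.03, with Ackr1 (2.49-fold) and P-selectin, Selp (2.10-fold), both genes of venous endothelium, higher. Clusters 21 and 36, both with Ackr1 and Selp among their leading genes, held 41.6% and 24.7% of that class in CIA+VFX and 33.6% and 15.7% in CIA, where cluster 17 held the most (50.7%). Of the 45 keratinocyte pairs 3 had an interval above 0 and 9 below it, and of the 16 in fibroblast-like and dermal papilla-like cells 4 and 1.

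To ask whether genes that stood apart in the model lay nearer to Cont with venlafaxine, the CIA cells were split at random into 2 equal parts so that the comparisons did not share counting noise. Over 15627 genes of all keratinocytes, log2 ratios of CIA to Cont and of CIA+VFX to CIA had a correlation of -0.346 across genes (-0.401 to -0.275 over 20 splits), and genes are not independent replicates. With the same CIA cells on both sides it was -0.541, where simulated libraries without any effect gave -0.616 shared and 0.00228 split. The covariances were -0.0724 with split cells and -0.0997 shared, against -0.0156 simulated shared. Of on average 1087 keratinocyte genes at least 2-fold apart in the model, 74.8% (72.1% to 77.4%) had a CIA+VFX level on the Cont side of CIA. For all keratinocytes this share was 64.1% after thinning, 66.8% with genes of at least 10 UMIs and 70.2% as a mean over cells. With genes of at least 200 UMIs it was 80.01%. The share was 79.6% in upper follicle keratinocyte-like, 76.3% in suprabasal keratinocyte-like and 73.2% in dermal papilla-like cells, and 65.2%, 58.2% and 54.1% after thinning, where T, NK and innate lymphoid-like cells had 65.5%, so this order of classes was not kept at a common depth. In the suprabasal keratinocyte-like class, inner root sheath keratins and Tchh summed to 621, 95.9 and 658 CPM in Cont, CIA and CIA+VFX, and cells or RNA of another type would by themselves place such genes on the Cont side. It was 69.8% in bulge-like, 68.1% in inner root sheath-like, 65.4% in fibroblast-like, 60.2% in macrophage and monocyte-like, 52.3% in matrix and hair shaft-like and 38.9% in skeletal muscle and satellite-like cells (50.5% with cells classed one by one). The noise-corrected squared distance of all keratinocytes was 0.278 between CIA and Cont, 0.186 between CIA+VFX and Cont and 0.0683 between CIA+VFX and CIA, so CIA+VFX keratinocytes lay nearer to CIA.

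Compared with Cont, vascular and granulocytic cells still took a larger share of the CIA+VFX suspension, and inner root sheath-like cells a smaller one. The ratio of shares was 0.539 for inner root sheath-like, 0.856 for matrix and hair shaft-like, 1.08 for bulge-like and 3.21 for sebocyte-like cells. It was 4.41 for vascular endothelial-like, 5.32 for neutrophil-like and 5.17 for mast cell and basophil-like cells, and 0.620 and 0.603 for macrophage and monocyte-like and T, NK and innate lymphoid-like cells (0.948 and 0.921 within the immune compartment). With cells classed one by one the matrix and hair shaft-like ratio was 1.35, and the neutrophil-like and mast cell and basophil-like ones were 2.56 and 2.98, while under the stricter filter the neutrophil-like ratio was 10.5. The hair shaft list was above Cont in matrix and hair shaft-like cells (median 1.03, 0.13 to 2.11, 13 of 23 genes higher and 2 lower). Its members Krt33b (146 against 4.26 CPM, 34.3-fold) and Krt81 (107 against 3.65, 29.3-fold) were higher in this class, as was Krtap22-2 (12.9-fold), which is outside that list. Serpinb2 (6.16-fold), Rasl11a (2.90-fold) and Lmo7 (2.27-fold) were lower there, and Lef1 had a log2 ratio of 0.64, with UMIs in 87.8% against 83.5% of cells (median depths 5066.5 and 9892.5) and in 1.94% and 1.20% of macrophage and monocyte-like cells (5246 and 6107).

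The wound and stress list stayed above Cont in upper follicle keratinocyte-like cells (0.95, 0.28 to 2.26) and suprabasal keratinocyte-like cells (1.52, 0.41 to 2.70), and the cornified envelope list had a median of -0.02 (median gene of suprabasal keratinocyte-like cells -0.17). Inner root sheath genes had a median of 0.38 (-0.21 to 0.52). The G2/M and S phase medians were 0.41 (0.32 to 0.51) and 0.22 (0.16 to 0.28) over all keratinocytes, 0.26 and 0.35 in upper follicle keratinocyte-like, 0.41 and 0.23 in inner root sheath-like and 2.30 and 1.25 in bulge-like cells. The bulge-like G2/M value was 0.60 with clusters 9 and 16 added and 0.35 with cells classed one by one. At a coarser clustering the inner root sheath-like values turned to -0.28 and -0.08, and thinning turned the upper follicle S phase value to -0.01. In bulge-like cells Pinlyp (15.7-fold), Mki67 (6.26-fold) and Tagln (5.13-fold) were above Cont, and the metallothionein Mt2 (3.31-fold), Ivl (3.07-fold) and Slc15a2 (2.94-fold) below. The stem cell list there had a median of 0.00 and p53 targets 0.32, and the median gene of bulge-like cells lay at 0.14. Medians of p53 targets were 0.10 in upper follicle keratinocyte-like, -0.13 in suprabasal keratinocyte-like, -0.02 in matrix and hair shaft-like, 0.07 in inner root sheath-like and 0.20 in dermal papilla-like cells.

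In fibroblast-like cells, Mup20 (31.3-fold), the phosphate hormone Fgf23 (14.3-fold) and Saa3 (12.7-fold) stayed above Cont, and Ndufa4l2 (3.65-fold), the interferon-induced GTPase Iigp1 (3.36-fold) and Sema3e (3.22-fold) below. The medians were 0.23 for p53 targets (-0.04 to 0.50), 1.36 for G2/M, 0.39 for S phase, 0.14 for collagen and matrix, -0.28 for Wnt, -0.18 for BMP and TGF-beta genes and -0.17 for growth factors, and the median gene lay at 0.12. In dermal papilla-like cells the heat shock genes Hspa1b (959 against 228 CPM, 4.20-fold) and Hspa1a (3.61-fold) and Pde10a (4.13-fold) were higher, and Mgp (5.43-fold), Ptn (4.93-fold) and Col8a1 (3.53-fold) lower. The dermal papilla signature had a median of 0.29 (0.13 to 0.61), Wnt genes 0.14, BMP and TGF-beta genes 0.07, growth factors 0.18, collagen and matrix genes -0.10, G2/M 0.07 and S phase -0.08.

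In macrophage and monocyte-like cells Chil3 (21.6-fold), Hp (15.1-fold) and Ly6c2 (11.9-fold) were above Cont, and Slc39a12 (21.3-fold), Tmem267 (11.2-fold) and Upb1 (10.9-fold) below, with cluster 1 at 54.1% against 9.93% of the class. Inflammatory cytokines and chemokines had a median of -0.43 (-0.63 to -0.07), the repair state list 0.20 and interferon response genes 0.16. The median gene of this class lay at 0.21. In T, NK and innate lymphoid-like cells Kcnma1 (4.68-fold), Carmil1 (4.49-fold) and the enkephalin precursor Penk (4.35-fold) were higher, and the chemokine Ccl4 (7.33-fold), Gzma (6.51-fold) and Klra8 (5.96-fold) lower, with cluster 50 at 5.74% against 1.47% of the class. Angiogenesis and endothelial activation genes had a median of -0.04 in vascular endothelial-like cells, where the median gene lay at 0.14.

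The genes of venlafaxine's targets were sparse in skin. Slc6a4, the serotonin transporter, had UMIs in 40.9% (20.7% to 63.6%), 28.6% (21.3% to 36.8%) and 42.2% (34.1% to 50.6%) of mast cell and basophil-like cells of Cont, CIA and CIA+VFX (9, 40 and 62 cells). Cluster 58, the one of its clusters with Slc6a4 among its leading genes, held 45.5%, 17.9% and 22.4% of this class, so the make-up of the class differed as well. The background was 0.1505%, 0.0417% and 0.125% in macrophage and monocyte-like cells, with median depths of 2721, 4272 and 3733 UMIs in the former and 6107, 4909.5 and 5246 in the latter. Slc6a4 had UMIs in 5.96%, 3.32% and 3.63% of all keratinocytes. Slc6a2, the noradrenaline transporter, had UMIs in 8.84%, 6.72% and 7.85% of bulge-like cells (median depths 11211, 7972 and 7959), against 0%, 0% and 0.188% of macrophage and monocyte-like cells. Over all kept cells the log2 ratios of CIA to Cont and of CIA+VFX to CIA were -0.19 and 0.69 for Slc6a4 and -0.01 and 0.29 for Slc6a2. The stem cell receptor gene Lgr5 had log2 ratios of 0.20 and 0.04 in bulge-like cells, and the former turned to -0.05 at a finer clustering.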

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

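Of the tests in this part, the share within the endothelial or neural crest compartment was chosen after the result was seen, and all others were planned. Each reported ratio, median and percent was recomputed under every alternative that applied and set against its own interval. A value is marked as turned, and counted so, where it changed direction and the reported interval excluded no difference (a share of 50% for Cont-side percents); where that interval included it, a value past no difference is marked as crossed. Direction held for most values of every kind. Named genes, Cont-side percents and shares within compartments left their intervals most often, and shares within compartments turned most often. For within-compartment shares the denominator differs by construction, and for every other value listed the cause was not tested. At Leiden resolution 0.8 no upper follicle or suprabasal class was named, so their values do not exist there. At least 200 UMIs per gene left the G2/M list of fibroblasts too short in 2 comparisons, and subtraction of free RNA was not applied to Cont-side percents. No paired analysis was possible because each group had 1 library, with replicate number 1 in every group.

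At Leiden resolution 2.5, 2 of 57 share ratios left their interval and 0 turned. Bulge was at 0.718 for CIA to Cont. Fibroblast was at 0.757 for CIA+VFX to Cont. When cells were classed one by one, 17 of 57 share ratios left their interval and 2 turned. Mast cell was at 2.41, neutrophil 3.296, dendritic 0.828 (turned), vascular 3.18, inner root sheath 0.313, matrix 0.752, upper follicle 1.06 and bulge 1.27 (turned) for CIA to Cont. Bulge was at 1.61, upper follicle 1.31, matrix 1.35 (crossed), inner root sheath 0.705, vascular 3.54, sebocyte 2.53, dendritic 0.6398, neutrophil 2.56 and mast cell 2.98 for CIA+VFX to Cont. Pericyte was at 1.01 and dermal papilla 0.827 for CIA+VFX to CIA. Within compartments, 25 of 45 share ratios left their interval and 9 turned. Bulge was at 1.07 (turned), upper follicle 1.84, suprabasal 1.52, matrix 0.631, inner root sheath 0.357, fibroblast 0.907 (turned), dermal papilla 0.765 (turned), macrophage 1.07 (turned) and sebocyte 1.84 for CIA to Cont. Pericyte was at 1.78, dendritic 1.32, T and NK 0.846 and skeletal muscle 1.22 for CIA to Cont. Mast cell was at 1.401, neutrophil 1.196 (crossed), skeletal muscle 0.629, T and NK 1.09 (turned), dendritic 1.01 (turned), pericyte 1.95, sebocyte 1.49, macrophage 0.889 and dermal papilla 1.34 (crossed) for CIA+VFX to CIA. Fibroblast was at 0.8801, inner root sheath 1.28, matrix 1.16, suprabasal 1.01, upper follicle 0.769 (turned) and bulge 0.857 (turned) for CIA+VFX to CIA. Bulge was at 0.919 (crossed), upper follicle 1.42, inner root sheath 0.459, macrophage 0.948, dendritic 1.33 (turned) and T and NK 0.921 for CIA+VFX to Cont. At Leiden resolution 0.8, 7 of 51 share ratios left their interval and 0 turned. Bulge was at 1.24 for CIA+VFX to CIA. Bulge was at 0.947 (crossed), inner root sheath 0.605, fibroblast 0.754 and macrophage 0.559 for CIA+VFX to Cont. Macrophage was at 0.835 and inner root sheath 0.311 for CIA to Cont. Under the stricter filter, 5 of 57 share ratios left their interval and 0 turned. Bulge was at 1.17 and neutrophil 10.5 for CIA+VFX to Cont. Neutrophil was at 1.22 (crossed), T and NK 0.887 and fibroblast 0.655 for CIA+VFX to CIA. Within the endothelial compartment, 2 of 6 share ratios left their interval and 3 turned. Vascular was at 1.42 and lymphatic 0.639 (turned) for CIA to Cont. Vascular was at 0.984 (turned) for CIA+VFX to CIA. Vascular was at 1.401 and lymphatic 0.621 (turned) for CIA+VFX to Cont. Within the neural crest compartment, 1 of 6 share ratios left their interval and 0 turned. Melanocyte was at 0.633 for CIA to Cont.

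After classing single cells, 1 of 27 ratios of cycling shares left their interval and 1 turned. Bulge was at 0.934 (turned) for CIA to Cont. Bulge was at 1.02 for CIA+VFX to Cont. At a minimum of 4 UMIs, 12 of 27 ratios of cycling shares left their interval and 0 turned. Bulge was at 1.79, dermal papilla 4.11, matrix 0.588, sebocyte 3.13, suprabasal 1.42 (crossed) and upper follicle 2.57 for CIA to Cont. All keratinocytes was at 1.14, upper follicle 1.73, sebocyte 3.05, fibroblast 2.14, dermal papilla 4.34 and bulge 1.91 for CIA+VFX to Cont.

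On classing each cell alone, 16 of 141 list medians left their interval and 5 turned. In bulge cells G2/M was -0.10 (turned), S phase in bulge -0.039 (turned), upper follicle 0.14 and inner root sheath 0.32 and dissociation in melanocyte -0.044 (turned) for CIA to Cont. Dissociation in melanocyte was -0.077, antigen presentation in all keratinocytes -0.55, BMP in dermal papilla 0.069 (crossed), p53 in bulge -0.064, S phase in bulge 0.33 and G2/M in bulge 0.45, upper follicle 0.032 (turned) and vascular -0.54 for CIA+VFX to CIA. G2/M in bulge was 0.35 and upper follicle 0.67, S phase in bulge 0.31, upper follicle 0.075 and inner root sheath 0.39, cornified envelope in suprabasal 0.37 (crossed), collagen in vascular -0.066 (turned) and dissociation in melanocyte 0.047 for CIA+VFX to Cont. As a mean over cells, 12 of 141 list medians left their interval and 1 turned. Cornified envelope in suprabasal was 0.14 (crossed), S phase in bulge 0.71 and inner root sheath 0.13 and G2/M in bulge 1.56 and upper follicle 1.16 for CIA to Cont. In bulge cells G2/M was 1.77 and S phase in bulge 0.82 for CIA+VFX to Cont. Antigen presentation in all keratinocytes was -0.27, S phase in upper follicle -0.40 and all keratinocytes 0.12 and G2/M in upper follicle -0.59, fibroblast 0.21 and vascular 0.071 (turned) for CIA+VFX to CIA. After thinning, 18 of 141 list medians left their interval and 1 turned. G2/M in bulge was 1.36, upper follicle 1.26, all keratinocytes 0.38 and vascular 1.04, S phase in bulge 0.50 and p53 in dermal papilla 0.38 for CIA to Cont. Interferon in lymphatic was 0.11, growth factors in fibroblast -0.40, S phase in bulge 0.82 and upper follicle -0.015 (turned) and G2/M in bulge 1.62, upper follicle 0.57 and vascular 0.67 for CIA+VFX to Cont. G2/M in upper follicle was -0.60 and fibroblast 0.25, S phase in upper follicle -0.57 and dermal papilla 0.19 (crossed), hair shaft in matrix -0.19 (crossed) and interferon in lymphatic 0.36 for CIA+VFX to CIA. With the same 5% of free RNA subtracted in every library, 4 of 141 list medians left their interval and 0 turned. An equal subtraction cannot show the effect of free RNA that differs between libraries. In bulge cells G2/M was 2.43 and fibroblast 1.78 for CIA to Cont. G2/M in bulge was 2.76 for CIA+VFX to Cont. Antigen presentation in all keratinocytes was -0.53 for CIA+VFX to CIA. At Leiden resolution 0.8, 4 of 117 list medians left their interval and 5 turned. In bulge cells G2/M was -0.24 (turned) and inner root sheath 0.31, S phase in inner root sheath 0.39 and collagen in vascular 0.042 for CIA+VFX to CIA. S phase in inner root sheath was -0.081 (turned) and G2/M in bulge 1.94 and inner root sheath -0.28 (turned) for CIA+VFX to Cont. G2/M in inner root sheath was -0.63 (turned) and S phase in inner root sheath -0.65 (turned) for CIA to Cont. Under the stricter filter, 1 of 141 list medians left their interval and 0 turned. G2/M in upper follicle was 0.21 for CIA+VFX to Cont. At Leiden resolution 2.5, 2 of 141 list medians left their interval and 0 turned. G2/M in upper follicle was 0.21 for CIA+VFX to Cont. S phase in inner root sheath was -0.059 (crossed) for CIA+VFX to CIA. Without removal of doublets, 7 of 141 list medians left their interval and 0 turned. G2/M in fibroblast was 0.24, collagen in vascular 0.37 (crossed) and dissociation in melanocyte 0.21 for CIA to Cont. Collagen in vascular was 0.16 and G2/M in fibroblast 0.74 and dermal papilla -0.31 for CIA+VFX to CIA. Dissociation in melanocyte was 0.026 for CIA+VFX to Cont. Under median-of-ratios scaling, 9 of 141 list medians left their interval and 0 turned. Cytokines in fibroblast was -0.60, collagen in fibroblast 0.0069 and S phase in fibroblast 0.098 and all keratinocytes 0.20 for CIA+VFX to CIA. S phase in all keratinocytes was -0.044 (crossed) and p53 in bulge 0.050 for CIA to Cont. Cytokines in macrophage was -0.64, BMP in fibroblast -0.27 and cornified envelope in suprabasal 0.21 (crossed) for CIA+VFX to Cont. Under TMM scaling, 5 of 141 list medians left their interval and 0 turned. S phase in fibroblast was 0.10, collagen in fibroblast 0.0088 and cytokines in fibroblast -0.60 for CIA+VFX to CIA. Cornified envelope in suprabasal was 0.23 (crossed) for CIA+VFX to Cont. S phase in all keratinocytes was -0.033 (crossed) for CIA to Cont. With genes of at least 200 UMIs, 2 of 139 list medians left their interval and 0 turned. G2/M in vascular was 1.03 for CIA to Cont. G2/M in vascular was 0.98 for CIA+VFX to Cont.

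With cells classed singly, 11 of 208 genes turned and 76 more left their interval. Tchh in matrix was -1.94 (turned), Plagl1 in bulge 0.30 (turned), Mki67 in bulge -0.35 (turned), Lef1 in matrix -0.10 (turned), Ivl in matrix -2.70 (turned) and Cux1 in bulge -0.23 (turned) for CIA to Cont. Ivl in matrix was 2.84 (turned), Pinlyp in bulge -2.31 (turned), Sox5 in bulge 0.21 (turned), Tchh in matrix 3.13 (turned) and Tchhl1 in matrix 2.14 (turned) for CIA+VFX to CIA. At Leiden resolution 0.8, 3 of 200 genes turned and 29 more left their interval. Pinlyp in bulge was -0.91 (turned), Mki67 in bulge -0.34 (turned) and Ednrb in fibroblast -0.082 (turned) for CIA+VFX to CIA. At Leiden resolution 2.5, 2 of 208 genes turned and 17 more left their interval. Ednrb in fibroblast was -0.0012 (turned) for CIA+VFX to CIA. Lgr5 in bulge was -0.051 (turned) for CIA to Cont. After thinning, 2 of 208 genes turned and 118 more left their interval. Krt32 in matrix was 0.29 (turned) and Ung in all keratinocytes -0.037 (turned) for CIA to Cont. Under median-of-ratios scaling, 1 of 208 genes turned and 34 more left their interval. Lgr5 in bulge was -0.010 (turned) for CIA to Cont.

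Without removal of doublets, 3 of 17 Cont-side percents left their interval and 0 turned. Bulge was at 65.3%, pericyte 55.3% (crossed) and suprabasal 70.4%. At Leiden resolution 0.8, 2 of 15 Cont-side percents left their interval and 0 turned. Vascular was at 56.9% and bulge 79.4%. Where every cell was classed alone, 9 of 17 Cont-side percents left their interval and 1 turned. Bulge was at 76.8%, dermal papilla 79.4%, lymphatic 61.5%, matrix 59.8%, pericyte 65.99% (crossed), sebocyte 59.8%, skeletal muscle 50.5% (turned), suprabasal 65.6% and upper follicle 71.4%. Vascular was at 68.2%. After thinning, 13 of 17 Cont-side percents left their interval and 0 turned. All keratinocytes was at 64.1%, vascular 55.1%, upper follicle 65.2%, T and NK 65.5%, suprabasal 58.2%, skeletal muscle 44.5%, sebocyte 53.4%, melanocyte 57.0% and inner root sheath 54.8%. Fibroblast was at 60.4%, dermal papilla 54.1%, dendritic 58.8% and bulge 62.3%. With genes of at least 10 UMIs, 13 of 17 Cont-side percents left their interval and 0 turned. Bulge was at 63.8%, dendritic 60.5%, dermal papilla 62.3%, fibroblast 59.5%, inner root sheath 57.5%, macrophage 55.8%, melanocyte 59.02%, sebocyte 62.3% and skeletal muscle 46.7%. Suprabasal was at 67.1%, T and NK 61.03%, upper follicle 68.6% and all keratinocytes 66.8%. With genes of at least 200 UMIs, 14 of 17 Cont-side percents left their interval and 0 turned. All keratinocytes was at 80.01%, upper follicle 88.1%, T and NK 83.3%, suprabasal 84.5%, sebocyte 78.4%, melanocyte 83.3%, matrix 64.6%, macrophage 64.2% and lymphatic 62.4%. Inner root sheath was at 77.6%, fibroblast 70.4%, dermal papilla 84.5%, dendritic 79.2% and bulge 79.4%. As a mean over cells, 8 of 17 Cont-side percents left their interval and 1 turned. Dermal papilla was at 58.8%, melanocyte 58.8%, pericyte 54.9% (crossed), sebocyte 58.7%, skeletal muscle 54.9% (turned), suprabasal 69.7%, upper follicle 74.4%, vascular 53.9% and all keratinocytes 70.2%. At Leiden resolution 2.5, 2 of 17 Cont-side percents left their interval and 0 turned. Upper follicle was at 82.04% and fibroblast 69.8%. Under median-of-ratios scaling, 2 of 17 Cont-side percents left their interval and 0 turned. Skeletal muscle was at 47.1% and suprabasal 78.7%. Under TMM scaling, 2 of 17 Cont-side percents left their interval and 0 turned. Suprabasal was at 78.8% and skeletal muscle 49.4%.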

Other observations

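Of the tests in this part, those on the share of keratinocytes, digestion yield, free RNA, cycling cells held outside the class and shared counting noise, and the pairs of list and class in this paragraph and the next, were chosen after the result was seen. Vascular endothelial-like cells of CIA carried more transcripts of dividing cells than those of Cont: all 26 measured G2/M genes were at least 1.5-fold higher (median log2 ratio 2.40, 1.298 to 3.16). The median was 1.04 after thinning and 1.03 with genes of at least 200 UMIs, and CIA+VFX stood at -0.31 against CIA (0.07 as a mean over cells). Cluster 17 held 63.4% of vascular endothelial-like cells in Cont and 50.7% in CIA, and cluster 21 held 20.2% and 33.6%. Collagen and matrix genes of these cells were higher in CIA+VFX than in CIA (0.78, 0.30 to 1.19, 19 of 35 genes higher and 1 lower), a median that was 0.04 at Leiden resolution 0.8 and 0.16 without removal of doublets. Lymphatic endothelial-like cells had more interferon response transcripts in CIA+VFX than in CIA (0.64, 0.40 to 0.82, 19 of 37 higher and 0 lower), where fibroblast-like cells had fewer (-0.47, -0.59 to -0.31, 0 higher and 14 of 40 lower).

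In fibroblast-like cells the inflammatory cytokines and chemokines had a median of 0.48 in CIA against Cont (-0.08 to 0.87, 14 of 32 higher and 3 lower) and of -0.49 in CIA+VFX against CIA (-0.60 to -0.21, 0 of 31 higher and 11 lower). In melanocyte-like cells of CIA, 11 of 18 melanin synthesis genes were at least 1.5-fold lower and 0 higher, with an interval that included 0 (median -0.77, -1.14 to 0.05), and with Oca2 at 741 against 2779 CPM (3.75-fold lower) and tyrosinase, Tyr, at 1107 against 3138 (2.83-fold lower). In CIA+VFX against CIA this median was 0.43 (-0.03 to 0.68), with Ednrb 1.99-fold and Tyr 1.88-fold higher. The same cells carried more dissociation and immediate early transcripts in CIA (0.65, 0.43 to 0.90, 16 of 27 higher), with Hspa1a 13.6-fold and Hspa1b 12.1-fold higher, and this median turned to -0.04 when cells were classed one by one. Antigen presentation genes over all keratinocytes had a median of 0.15 in CIA against Cont (-0.27 to 0.86), with H2-T23 2.43-fold and Tap2 2.22-fold higher. In CIA+VFX against CIA it was -0.40 (-0.51 to -0.32), with Cd86 2.84-fold and H2-Eb1 1.56-fold lower. Cd86 and H2-Eb1 were leading genes of immune clusters 24 and 8, and the immune compartment was 25.9% of CIA+VFX and 34.5% of CIA cells. Cells or RNA of immune types are thus not excluded for these genes.

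Vascular endothelial-like cells were 3.93-fold more of the kept cells in CIA than in Cont. A lower share of keratinocytes would raise all other classes alike, and share ratios of the 13 non-epithelial classes differed by up to 12.2 times, from neutrophil-like to melanocyte-like cells, which argues against it as the whole cause of these differences. That spread does not use the vascular endothelial ratio itself. The epithelial compartment was 36.9% of Cont and 27.4% of CIA cells, too small a fall to raise all other classes 3.93-fold. The filter on cells is argued against too, since 14 vascular endothelial markers had a median CPM ratio of 2.56 (2.12 to 3.63) over all barcodes without any filter. A different yield of endothelial cells in tissue digestion cannot be told apart from a difference in the skin, because there was only 1 library per group. More vessels in the skin of the model, the biological reading, was not tested by any other measure.

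G2/M genes in bulge-like cells stood at a median of 2.11 in CIA against Cont. Different clusters making up the class are argued against, since 80.5% of its cells, in the library where this was lower, lay in clusters whose own interval was above 1. Free RNA of cycling cells is argued against as well: the list gained 581 CPM in bulge-like cells but -20.3 CPM in dermal papilla-like cells. Cycling cells held outside the class by the clustering cannot be told apart from more dividing cells within the bulge-like class. The median was 0.33 (0.23 to 0.45) with clusters 9 and 16 counted in. But these clusters then gave 83.7% of the list UMIs of Cont and 69.7% of those of CIA, so they largely set that value. With each cell classed by itself, the G2/M median of the bulge-like class turned to -0.10. The excess was thus not seen once clustering did not set the class. More dividing bulge-like cells in the model thus stays a hypothesis. It covers the bulge, outer root sheath and companion layer together, which the class does not separate. A count of Ki67-positive cells in each of these parts in tissue sections would test it.

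Keratinocyte genes of CIA+VFX lay on the Cont side of CIA for 74.8% of the genes that stood apart in the model (64.1% after thinning to a common depth). Shared counting noise of the CIA library is argued against by a covariance of -0.0724 with split cells, and the highest of 20 splits was -0.0624. If the CIA library alone stood apart, CIA+VFX would lie close to Cont, but its squared distance from Cont was 2.72 times that from CIA (2.53 to 2.96). This speaks only against CIA being the sole library apart. Something particular to the CIA library, on top of a difference shared with CIA+VFX, would also place genes on the Cont side. Splitting the CIA cells removes shared counting noise only, so that cause stays open. The pool also differed in make-up (inner root sheath-like cells at 6.93%, 1.84% and 3.73% of kept cells and clusters 9 and 16 at 5.91%, 2.63% and 7.08% in Cont, CIA and CIA+VFX) and the CIA library in mitochondrial UMIs (medians of 2.32%, 1.42% and 2.40%), so make-up, cell quality and the pools of mice stay open and untested as causes. A partial return of keratinocyte transcripts with venlafaxine is thus a hypothesis, found and examined on the same 3 libraries, and libraries of several separately sampled mice per group would test it.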
